A study of Mus musculus with 4 samples.

How the data were processed

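Tracheal epithelial cells of 2 control mice (Mettl3fl/+) and 2 Mettl3 cKO mice (Mettl3fl/fl) were profiled by 3′ droplet sequencing (10x chemistry v3.1, per the labels), with 1 library per mouse. For each library the authors deposited a matrix of raw UMI counts per gene and barcode, and a matrix of tdTomato counts for a list of barcodes. Cell Ranger and mm10 are named per the submitters' processing notes, and their versions are not given in the sources used here. The deposited counts carry no normalization or batch correction. The tdTomato counts were deposited with no barcode under 15, 14, 8 and 17 in control replicates 1 and 2 and cKO replicates 1 and 2, so the lists had a different floor in each library. Of 4893 listed barcodes, 6 in control replicate 2 were not in its gene matrix. Listed barcodes were taken as traced and all others as untraced, so a cell with little tdTomato counts as untraced.

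Barcodes with at least 500 genes and under 20% mitochondrial UMIs were kept (8895 of 10503). Scrublet scored doublets, and the highest scores were left out at 0.8% per 1000 barcodes (171), because its own threshold marked 0.461%. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes without sex-linked genes gave 30 principal components, and Leiden clustering ran on 15 neighbours at resolution 1. In 6 clusters, over 25% of barcodes held at least 2 UMIs each of ciliated, immune and basal markers (31.7% to 97.4%, against 0% to 8.1% in the other 28). Their 1510 barcodes were left out as mixed profiles. The 28 clusters of the remaining 7214 cells were named from marker lists by their mean log2 difference (over 0.25, offset 5 CPM) from the mean of the other clusters. A name needed at least 3 markers detected in 20% of the cells, or 5 where none was among the 10 leading genes. Names such as basal-like are assignments from markers, not sorted types, and 2 clusters without a clear class stayed unnamed. No integration across libraries was applied. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9.

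UMIs were summed per library, class and tracing status, and a class was tested only with at least 20 cells in every library. This left out traced ciliated-like, untraced secretory-like and untraced ciliated-like cells, and hillock-like cells. The genotype comparisons were fitted in edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with TMM scaling, its filter on low counts and Benjamini-Hochberg adjustment. The standard error of a log2 fold change is its size over the root of the F statistic. Levels in CPM are scaled by TMM, except for Xist, Ddx3y and Ces1f. The tests that set traced against untraced or basal-like against secretory-like cells fitted all libraries of both classes with library as a term, with genes at or near 0 in a class given no fold. Shares of classes were tested in edgeR on cell counts. A set of 38 gene lists was tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were measured. Camera compares a list with all other genes, and "with an estimated correlation" gives its p with the correlation between members estimated from the libraries. Fry of limma and DESeq2 1.42.0 were run as other tools. On simulated counts, 7 of 7 changed lists were found and 0 of 7 unchanged lists. The simulated genes were drawn independently, so this does not test the lists where members are correlated. Each simulated gene had the spread typical of its level, and changes were placed only in genes above a floor of CPM. The share of genes changed by log2 1 that was recovered was 69.0% in traced basal-like, 31.0% in traced secretory-like, 28.9% in untraced basal-like and 19.0% in ciliated-like cells, and by log2 2 it was 100%, 95.0%, 90.9% and 82.0%.

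Lists, markers, comparisons and most alternatives were fixed before the data were examined. The genes named are Mettl3, the 10 largest changes each way among those past an adjusted p of 0.05 with a mean of at least 20 CPM, and up to 4 members of each list. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not passing, and other tests name up to 5 genes per direction. Members of lists are named by p. Xist, Ddx3y, Krt5, Trp63, Cd74, Ccl20 and genes that lead a cluster were chosen after their values were seen. Chosen after seeing the data were the rate of doublets, the mixed-profile step, the reference for naming, the common tdTomato floor of 17, the clusters left out, the test of ciliated-like cells traced and untraced together, and list tests beyond the traced classes. The alternatives were RLE scaling, no filter on low counts, DESeq2, the replicate number as a block, each library left out, a stricter filter on cells (1000 genes, 10% mitochondrial), doublets kept, mixed profiles kept, a resolution of 1.5, the other naming, the common floor, thinned cells, and traced and untraced cells together. Replicate numbers coincide with sex as read from Xist and Ddx3y, so the fit with that block is also the fit with sex as a term. It has more terms for the same 4 libraries, so less is left to estimate the spread between animals. The median log2 fold change of all genes lay within 0.02 of 0 under TMM and RLE scaling.

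Total UMIs per library ranged from 32945287 to 59319167. Those of traced basal-like cells were 21468947, 14823087, 13586754 and 15284301. Shares of single libraries have exact (Clopper-Pearson) 95% intervals, which cover counting error only and not the differences between animals. Annotation positions are from the mm10 gene set. Reads shared between near-identical genes (histones, Sprr2 and class II genes) could not be told apart from the deposited counts.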

Results

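The RNA of single cells was measured in the tracheal epithelium of 4 mice. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Both Mettl3 alleles were floxed in the 2 conditional knockout (cKO) mice and 1 allele in the 2 control mice. All carried a Cre recombinase expressed from the Krt5 gene, which is active in airway basal cells, and a tdTomato reporter that marks cells in which Cre has acted and their descendants. Traced (tdTomato-positive) and untraced cells were mixed in equal parts before loading, so their ratio was set by the sort and is not compared here. The comparisons ask which genes and cell types differ between cKO and control cells of the Krt5 lineage.

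The libraries held 32945287 UMIs in 1886 barcodes of control replicate 1, 59319167 in 3677 of control replicate 2, 49057529 in 2629 of cKO replicate 1 and 44016625 in 2311 of cKO replicate 2. After filtering, 1562, 1916, 2025 and 1711 cells were analysed in the same order, of which 1082, 978, 883 and 790 were traced. Control replicate 2 lost 1239 barcodes that held RNA of several cell types together, against 58, 47 and 166 in control replicate 1, cKO replicate 1 and cKO replicate 2. The median depth of the analysed cells was 17950.5, 16717, 18219 and 21176 UMIs.

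Mettl3 (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128 on the minus strand of mm10, protein coding) was detected in every library. In traced basal-like cells it stood at 11.5 and 12.8 CPM in the controls and at 9.57 and 12.1 CPM in the cKO mice, from 245, 197, 129 and 181 UMIs. The log2 fold change was -0.17 (SE 0.18, edgeR adjusted p = 0.774), within the spread between replicates. It was -0.42 (SE 0.30, adjusted p = 0.893) in traced secretory-like cells and -0.67 (SE 0.36, adjusted p = 0.981) in untraced basal-like cells. The floxed exons are not named in the labels and 3′ tags may lie outside them, so these levels check neither the deletion nor the labels. Xist, expressed from the inactive X, stood at 9.1, 1662, 2.8 and 1467 CPM, and the Y-linked Ddx3y at 56.1, 0, 56.0 and 1.6 CPM. Replicate 1 was therefore male and replicate 2 female in both groups. Against the control of the same sex, Mettl3 was lower in each cKO mouse in traced basal-like, traced secretory-like, untraced basal-like and all ciliated-like cells. In traced basal-like cells, before TMM scaling, it stood at 9.5 against 11.4 CPM in males and 11.8 against 13.3 CPM in females. Classes with too few cells for a test did not all follow. Mettl3 was higher in the cKO mouse in traced hillock-like cells of females (7.6 against 4.2 CPM, 4 and 3 UMIs). The same held in untraced secretory-like cells of males (4.3 against 2.5 CPM, 49 and 1 UMIs).

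Basal-like cells, the Krt5 and Trp63 expressing stem cells of this epithelium, made up 80.9% ± 7.20 (SD, n = 2) of traced control cells and 69.6% ± 2.35 of traced cKO cells. Secretory-like cells made up 11.5% ± 5.97 and 15.9% ± 6.57, and ciliated-like cells 2.49% ± 1.83 and 2.93% ± 1.58. Hillock-like cells, a stratified Krt13 expressing population, were 17.8% of the traced cells of cKO replicate 1 (exact 95% confidence interval 15.3 to 20.5) and 2.41% of those of cKO replicate 2, against 4.34% and 3.48% in the controls. Among untraced cells, tuft-like cells, a chemosensory type, were 14.6% in control replicate 1 (11.5 to 18.1) and 0.426% in control replicate 2, close to the 0.196% ± 0.030 of the cKO mice. Immune-like cells were 38.7% of untraced cells in cKO replicate 2 (35.5 to 41.9) and 5.08% in cKO replicate 1, against 7.56% ± 3.33 in the controls. No class passed edgeR's test of shares in traced cells, where the adjusted p was 0.672 for basal-like (log2 -0.22, SE 0.27), secretory-like (0.46, SE 0.61) and hillock-like cells (1.37, SE 1.12) and 0.794 for ciliated-like cells (0.23, SE 0.82). None passed in untraced cells, where tuft-like cells came nearest (log2 -5.15, SE 1.74, adjusted p = 0.0749) and alone had an unadjusted p under 0.05. The tuft-like share passed without control replicate 2 (log2 -6.12, adjusted p = 0.0320), which leaves only the control with many such cells. Without control replicate 1 too few such cells were left for a test, and with sex as a term the log2 was -3.83 (SE 2.20, adjusted p = 0.781). With clusters named against all other cells, 418, 504, 353 and 489 traced cells were basal-like, and their log2 fold change was 0.18. With the barcodes of several cell types kept it was 0.15, and that of secretory-like cells -1.01. Of those barcodes, 1224 of control replicate 2 were then named secretory-like, so its traced secretory-like cells went from 154 to 1080. Control replicate 1, cKO replicate 1 and cKO replicate 2 then had 79, 104 and 163. The direction of these shares thus depends on how cells are named and filtered. Leaving out a library turned or multiplied other changes. Hillock-like cells had -0.70 without cKO replicate 1. Ciliated-like cells had -0.37 without control replicate 1, 1.27 without control replicate 2, 0.70 without cKO replicate 1 and -0.45 without cKO replicate 2, and secretory-like cells 0.01, 1.12, 0.83 and -0.04 in the same order. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333.

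**Figure D1:**
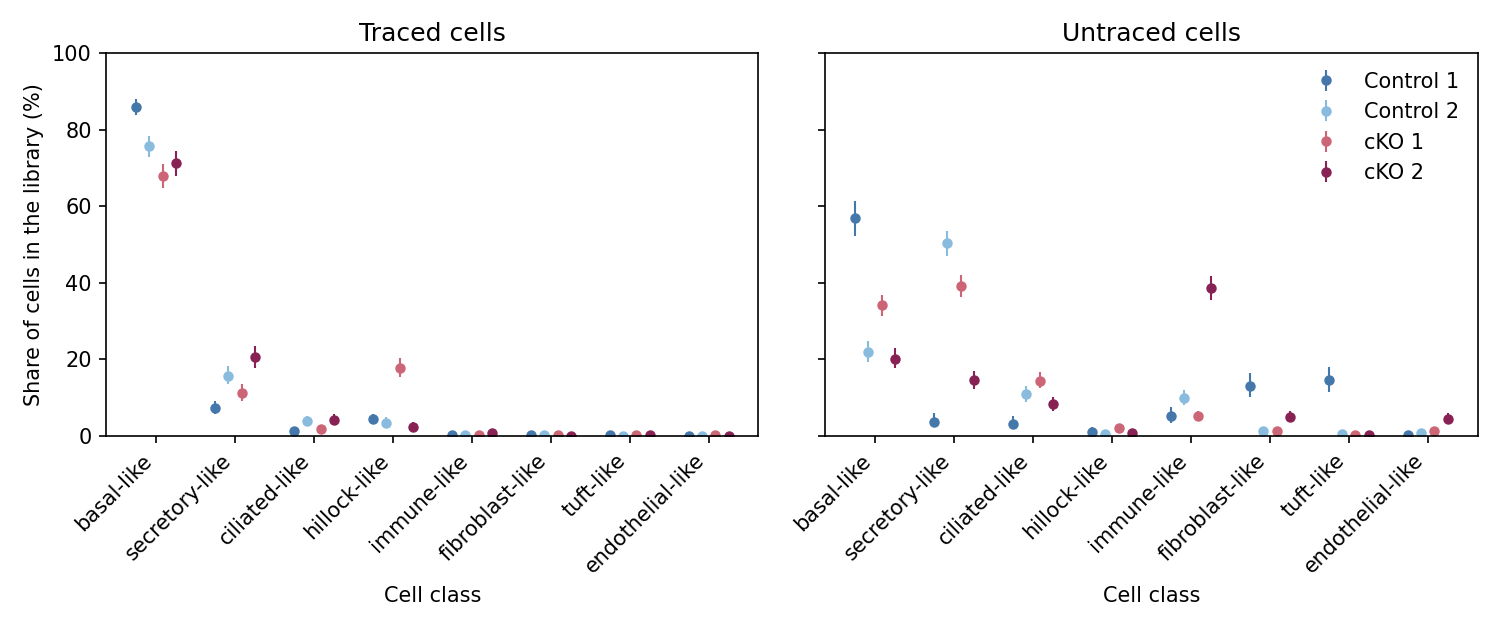
Share of each cell class among traced (left) and untraced (right) cells of each library, in percent, with exact 95% binomial confidence intervals as bars. The spread between replicates exceeds the counting intervals for hillock-like cells in cKO replicate 1, immune-like cells in cKO replicate 2 and tuft-like cells in control replicate 1. Replicates also lay outside each other's intervals in larger classes. In control replicates 1 and 2, traced basal-like cells were 86.0% and 75.8%, and untraced secretory-like cells 3.75% and 50.3%.

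In traced basal-like cells, genes of DNA replication and mitosis formed the lists with the smallest p. Hmmr (ENSMUSG00000020330, chromosome 11, 40701395 to 40733422), a spindle-associated protein, stood at 7.49 ± 0.737 CPM (SD, n = 2) in controls and 21.9 ± 0.984 in cKO mice (log2 1.54, SE 0.15). Cenpf, a kinetochore protein, stood at 23.5 ± 2.22 and 54.7 ± 1.73 CPM (log2 1.22, SE 0.13), and Rrm2, a subunit of ribonucleotide reductase, at 8.51 ± 0.499 and 20.7 ± 2.80 CPM (log2 1.28, SE 0.16). The G2 and M phase list rose, with 49 of its 52 measured members above 0 and a median log2 fold change of 0.99 (limma camera adjusted p = 2.26e-62). Its adjusted p = 0.597 with an estimated correlation. The S phase list rose, with 39 of 39 members above 0 and a median of 0.79 (adjusted p = 3.31e-30; adjusted p = 0.597 with an estimated correlation). Adjusted over the list alone, 39 G2 and M phase genes and 21 S phase genes were higher, against 0 adjusted over all genes. The proliferating cluster, led by Cenpf and Hmmr, held 3.23% and 4.18% of traced basal-like cells in the controls and 10.0% and 6.75% in the cKO mice. Without that cluster the medians were 0.39 for G2 and M phase (adjusted p = 1.72e-06) and 0.67 for S phase (adjusted p = 1.80e-15), and with clusters named against all other cells they were 0.196 (25 of 37 above 0, adjusted p = 0.0173) and 0.432 (37 of 38, adjusted p = 9.35e-07).

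Genes of cholesterol synthesis formed another group, which also rose as a list in untraced basal-like cells (below). Fdps, which makes farnesyl diphosphate, stood at 26.0 ± 0.064 CPM in controls and 50.9 ± 1.20 in cKO mice (log2 0.97, SE 0.11), and Cyp51, the lanosterol demethylase, at 24.8 ± 3.34 and 44.8 ± 2.05 (log2 0.85, SE 0.14). The log2 fold changes of Msmo1 and Idi1, which act in the same pathway, were 0.80 and 0.96. The list rose, with 22 of 23 members above 0 and a median of 0.43 (camera adjusted p = 1.55e-11; adjusted p = 0.597 with an estimated correlation), and 8 members were higher adjusted over the list alone, against 0 over all genes.

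Keratins and markers of stratified cells passed as lists here and in untraced basal-like cells (below), with few members passing alone here. Krt14, a keratin of activated and squamous basal cells, stood at 45.5 and 75.3 CPM in the controls and at 216 and 282 CPM in the cKO mice (log2 2.04, SE 0.27, edgeR adjusted p = 0.133). Krt6a had a log2 fold change of 1.10 (SE 0.36), Krt17 of 0.92 (SE 0.32), Krt4 of 0.70 (SE 0.22) and Ecm1, an extracellular matrix protein, of 0.87 (SE 0.27). Anxa8, an annexin, had 0.52 (SE 0.16). The keratin list (13 of 15 members above 0, median 0.32, adjusted p = 3.63e-05) and the hillock and squamous list (17 of 18, median 0.58, adjusted p = 2.56e-05) rose, with 5 genes in common. The adjusted p = 0.597 with an estimated correlation for each. Adjusted over the list alone, 1 keratin, Krt14, and 0 hillock members were higher, against 0 over all genes. Markers that define basal identity did not pass as a list (adjusted p = 0.179), with Krt5 at log2 0.32 and Trp63 at -0.28.

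**Figure D2:**
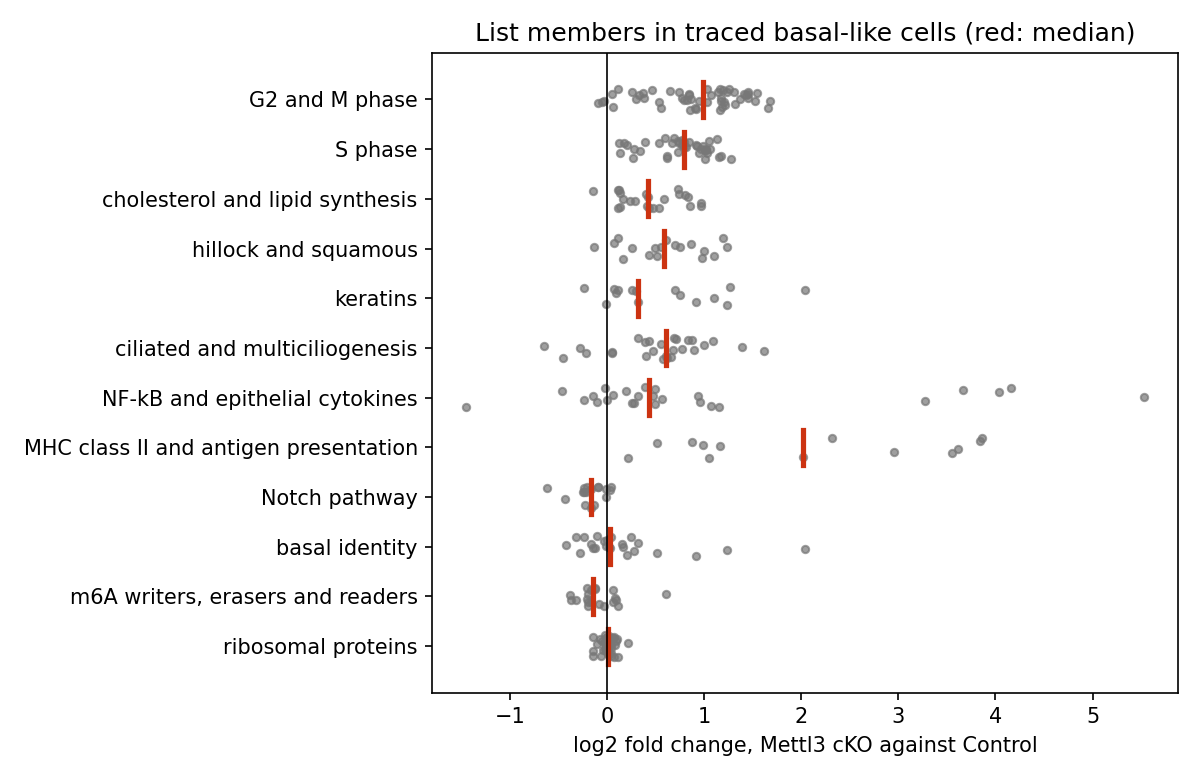
Log2 fold change of cKO against control in traced basal-like cells for each measured member of 12 gene lists; grey points are genes and red bars the list medians. The medians of G2 and M phase (0.99) and S phase (0.79) lie right of 0, and that of the ribosomal proteins (0.01) lies near it.

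MHC class II genes were highest in 1 animal. H2-Ab1 stood at 3.82, 18.6, 9.35 and 250 CPM in control replicates 1 and 2 and cKO replicates 1 and 2, and the invariant chain Cd74 at 7.50, 52.4, 17.5 and 846 CPM. The list of MHC class II and antigen presentation genes, called the MHC class II list, also holds class I genes such as H2-K1, H2-D1 and B2m. It rose, with 13 of 13 members above 0 and a median of 2.02 (camera adjusted p = 9.82e-05, or 0.720 with an estimated correlation). No member had both cKO mice above both controls, 0 members were higher adjusted over the list alone, and without cKO replicate 2 the list lay lower (adjusted p = 0.255). Against the control of the same sex, 10 of 13 members were higher in cKO replicate 1 and 13 of 13 in cKO replicate 2, and with sex as a term the list rose (median 1.75, adjusted p = 1.88e-18). The NF-kB and epithelial cytokine list rose (20 of 26, median 0.43, adjusted p = 9.07e-07; adjusted p = 0.684 with an estimated correlation), with 11 members higher in both cKO mice than in both controls, and its call ended without cKO replicate 2 (adjusted p = 0.123). In it Tnfaip3, a feedback inhibitor of NF-kB, stood at 27.7 ± 7.72 and 61.3 ± 11.4 CPM (log2 1.15, SE 0.23). The neutrophil and inflammation genes S100a8 and S100a9 stood at 0.145 and 0.369 CPM in controls and 6.68 and 6.01 CPM in cKO mice, S100a8 from 1, 3, 15 and 13 cells. Both lead an unnamed cluster of low depth with 11, 23, 18 and 50 cells, and RNA from such cells was not excluded as their source. With them, 5 members of the list were higher and 1 lower adjusted over the list alone. Immune cell markers rose (8 of 9, median 1.04, adjusted p = 9.82e-05; adjusted p = 0.597 with an estimated correlation; 2 higher adjusted over the list alone) and lost the call without cKO replicate 2 (adjusted p = 0.107), without the proliferating cluster (0.273, median 0.47 over 5 members) and under the other naming (0.420, median 0.45). Tyrobp, an adaptor of myeloid receptors, stood at 0.458 and 2.06 CPM and Cd52, a lymphocyte surface protein, at 1.65 and 3.86 CPM. In cKO replicate 2, cluster 4 held 72.7% of traced basal-like cells, against 1.08%, 7.29% and 1.33% in control replicate 1, control replicate 2 and cKO replicate 1.

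The ciliated and multiciliogenesis list rose (23 of 27, median 0.61, adjusted p = 0.000117; adjusted p = 0.720 with an estimated correlation), and lost the call without control replicate 1 (adjusted p = 0.222). Mlf1 (ENSMUSG00000048416, chromosome 3, 67374097 to 67400003), a gene of ciliated cells, stood at 9.57 ± 0.198 and 25.1 ± 0.048 CPM (log2 1.39, SE 0.13). It was the only member higher adjusted over the list alone, while Rfx2, a transcription factor of ciliated cells, had a log2 fold change of -0.65 (SE 0.15). The Notch list fell (2 of 17 above 0, median -0.17, adjusted p = 0.0349; adjusted p = 0.720 with an estimated correlation). The ligands Jag1 and Jag2 had log2 fold changes of -0.21 and -0.25, the coactivator Maml1 -0.43 and the receptor Notch3 -0.61, and 0 members passed adjusted over the list alone. The Notch call ended without control replicate 2 (adjusted p = 0.0800), without cKO replicate 2 (0.224), without the proliferating cluster (0.0514) and under the other naming (0.0802), the last 2 with medians of -0.152 and -0.145, near the -0.17 of all cells.

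The m6A writers, erasers and readers did not pass as a list (6 of 20 above 0, median -0.15, adjusted p = 0.0927). They passed as lower with untraced cells added (0.0424, median -0.13), under the other naming (0.0327, median -0.14) and without control replicate 1 (0.0255, median -0.18). Rbm15b, a writer subunit, stood at 37.9 and 29.0 CPM (log2 -0.38, SE 0.12) and the demethylase Alkbh5 at 98.8 and 76.2 CPM (log2 -0.37, SE 0.13). The interferon list did not pass (adjusted p = 0.221), and passed as higher without cKO replicate 1 (4.47e-22), as lower without cKO replicate 2 (0.00238), and as higher with sex as a term (0.0466). The other lists that did not pass were tight junctions and glycolysis (adjusted p = 0.0628 each), mitochondrially encoded genes (0.0746), SOCS feedback (0.151), oxidative phosphorylation (0.179), apoptosis (0.181), club and secretory genes and heat shock (0.210 each), and tuft, ionocyte and neuroendocrine markers (0.222). Some of these passed as higher under an alternative. With untraced cells added and without the proliferating cluster, tight junctions (0.0432 and 0.0344), glycolysis (0.0302 and 0.0425) and mitochondrially encoded genes (0.0424 and 0.0151) did. Under the other naming tight junctions (0.0293), mitochondrially encoded genes (0.0152) and oxidative phosphorylation (0.0173) did. Without control replicate 1 oxidative phosphorylation (8.27e-06) and glycolysis (0.0155) did, without control replicate 2 mitochondrially encoded genes (0.0314), without cKO replicate 1 oxidative phosphorylation (0.0297) and apoptosis (0.0401), and without cKO replicate 2 tight junctions (0.00655). Heat shock passed as lower without control replicate 2 (0.0136) and without cKO replicate 2 (0.00308), and club genes without control replicate 1 (0.0396). Immediate early genes had 0.534, Wnt 0.551, NRF2 targets, extracellular matrix and goblet genes 0.627 each, sex-linked genes 0.776, p53 targets 0.878, EGFR response 0.930, ribosomal proteins and the unfolded protein response 0.947 each, and BMP response 0.978. The goblet list had a median of 0.15 and a mean of -0.40. The median of the NRF2 list (0.02), of the EGFR list (0.10) and of the ribosomal list (0.01) lay above 0 and the test pointed lower, and the sex-linked list (median -0.09) pointed higher. Markers of fibroblasts, muscle, endothelium, nerve and erythroid cells had too few measured members for a test.

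Over all genes in traced basal-like cells, edgeR called 0 of 13645 at an adjusted p under 0.05. At an unadjusted p under 0.05, 827 were higher and 613 lower, and DESeq2 called 135 (117 higher, 18 lower). A fit with the animals' sex as a term leaves 1 degree of freedom for the spread between animals. With that fit edgeR called 141 (132 higher, 9 lower), of which 29 were members of the cell cycle lists and 97 were also called by DESeq2. Without cKO replicate 1 it called 157 and without cKO replicate 2 158. The smallest p among higher genes belonged to Mlf1, Hmmr, Aspm, Cenpf and Gm15446 (adjusted p = 0.133 each), and among lower genes to Arhgap24, Angptl4, Ifi27l2a, Tsc22d3 (0.133 each) and Gm16867 (0.196). Arhgap24 (ENSMUSG00000057315, chromosome 5, 102481391 to 102897937), a GTPase-activating protein, stood at 14.3 ± 2.04 and 4.12 ± 0.360 CPM (log2 -1.79, SE 0.20). Tsc22d3, a glucocorticoid-induced gene, stood at 218 ± 18.1 and 90.8 ± 12.7 CPM (log2 -1.26, SE 0.16), the interferon-induced Ifi27l2a at 100.3 ± 7.39 and 42.3 ± 6.71 (log2 -1.25, SE 0.16), and Angptl4, an inhibitor of lipoprotein lipase, at 9.25 ± 0.455 and 2.71 ± 0.254 (log2 -1.77, SE 0.23). Gm15446 (log2 3.59) and Gm16867 (log2 -4.69) are predicted genes. The groups did not overlap for 5889 genes, 43.2%, where chance gives 33.3% if the libraries are exchangeable. Sex differences shared by both groups would change that value, so the 2 shares are not a test. In simulated counts the same test recovered 69.0% of genes changed by log2 1 and 100% of those changed by log2 2. Those genes lay above a floor of CPM, and each had the spread typical of its level.

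**Figure D3:**
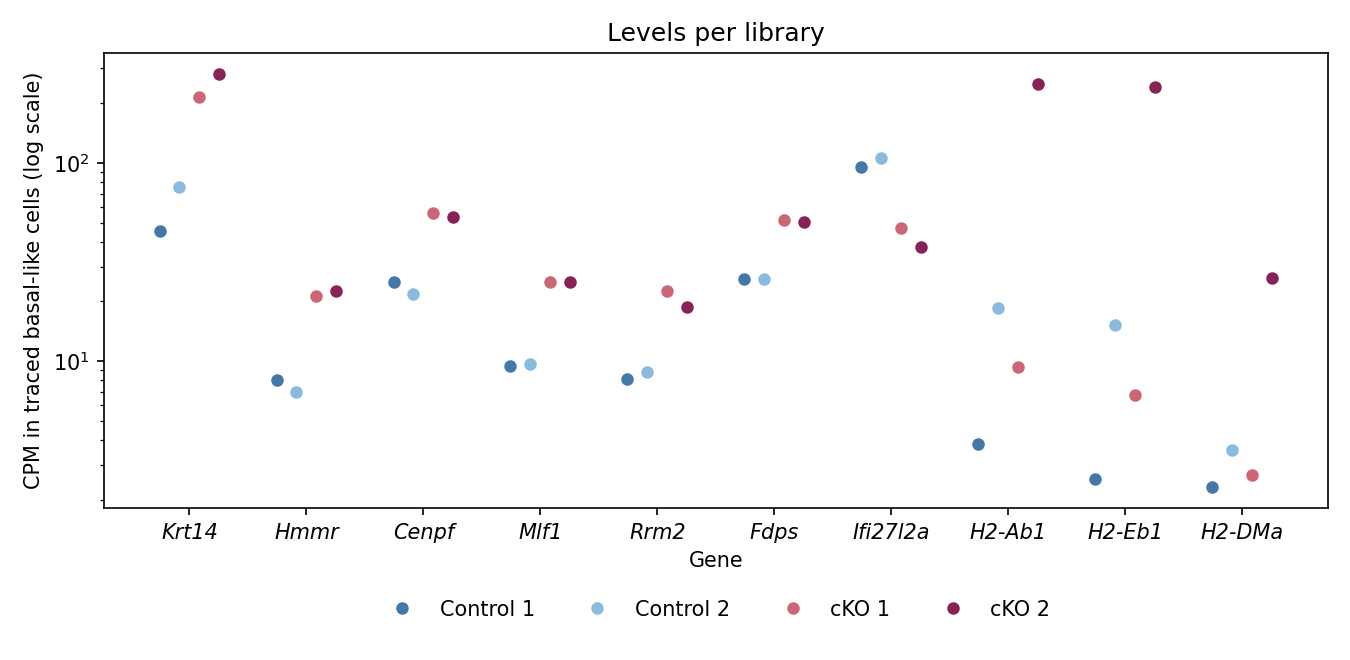
Level of 10 genes in traced basal-like cells of each library, in CPM on a log scale, with a point per library. Hmmr, Cenpf, Mlf1, Rrm2, Fdps and Krt14 lie higher in both cKO libraries than in both controls, and H2-Ab1, H2-Eb1 and H2-DMa are highest in cKO replicate 2.

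In traced secretory-like cells, Fabp5, a fatty acid binding protein, stood at 19.5 and 36.6 CPM in the controls and 332 and 315 CPM in the cKO mice (log2 3.5, SE 0.31, edgeR adjusted p = 0.0800). Sprr2a3, a cornified envelope protein, stood at 6.75 ± 0.428 and 39.8 ± 9.0 CPM (log2 2.58, SE 0.26, adjusted p = 0.0883), and the sulfotransferase Sult1b1 at 25.8 ± 0.047 and 66.6 ± 3.54 (log2 1.37, adjusted p = 0.191). The ubiquitin-like Ubd stood at 1.77 and 92.4 CPM and the transcription factor Spib at 0.936 and 40.6 CPM (adjusted p = 0.191 each). Fabp5, Ubd and Spib are among the leading genes of cluster 25, which held 7 and 3 traced cells in the cKO mice and 0 in the controls. Lower were the kinase Dapk1 (log2 -1.05), the urokinase receptor Plaur (-1.42), the chemokine Cxcl15 (-1.93, each adjusted p = 0.319), the nuclear receptor Nr4a3 (-2.01, 0.470) and the ephrin receptor Epha2 (-0.97, 0.514). None passed, and edgeR called 0 of 11195 genes, against 380 higher and 246 lower at an unadjusted p under 0.05. DESeq2 called 17 and edgeR with sex as a term 70. Without cKO replicate 1 edgeR called 264, and without cKO replicate 2 14.

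Of 31 lists tested in traced secretory-like cells, 5 rose, and for each the adjusted p = 0.836 with an estimated correlation. The hillock and squamous list rose (13 of 14 members above 0, median 0.37, camera adjusted p = 7.88e-06), where Krt13 stood at 12.7 ± 12 and 35.9 ± 10.4 CPM, Krt4 had log2 0.61 and Ecm1 0.99. With the barcodes of several cell types kept, that call ended (adjusted p = 0.641, median 0.01). Most traced secretory-like cells of control replicate 2 were then such barcodes. The NF-kB list rose (18 of 22, median 0.54, adjusted p = 0.000556), where the chemokine Ccl20 stood at 92.1 ± 71.5 and 881 ± 281 CPM. It lost the call without control replicate 1 (0.265), without cKO replicate 2 (0.337) and without cluster 25 (0.263, median 0.24), which Ccl20 also leads. The MHC class II list rose (13 of 13, median 1.36, adjusted p = 0.000556), with Cd74 at 0.415, 132, 86.4 and 1506 CPM. It lost the call without control replicate 1 (0.149), lay lower without cKO replicate 2 (0.0691), and rose with sex as a term (2.02e-27). The apoptosis list rose (20 of 26, median 0.18, adjusted p = 0.00850), with Fadd, an adaptor of death receptors, at 5.19 and 12.2 CPM (log2 1.22), the caspase inhibitor Birc3 at log2 1.07, and the BH3-only genes Bcl2l11 at 0.94 and Bik at 0.68. Its call ended without control replicate 1 (0.149) and without cKO replicate 2 (0.433). The basal identity list rose (18 of 22, median 0.24, adjusted p = 0.0168), with Itga6 at log2 0.65, Krt5 at 0.54, Pdpn at 0.45 and Sox2 at 0.41, and lost the call without control replicate 1 (0.242), without cKO replicate 1 (0.557), without cluster 25 (0.0768, median 0.20) and with untraced cells added (0.441, median 0.02), and lay lower with the barcodes of several cell types kept (0.261, median -0.38). The other 26 had adjusted p from 0.0954, for keratins, to 0.989, with S phase at 0.621 and G2 and M phase at 0.979. With untraced cells added, 8 of 33 lists passed, 6 as higher and 2 as lower, among them the m6A list as lower (0.0207). With sex as a term interferon genes (0.00152) and keratins (0.0174) passed as higher. Adjusted over the list alone, 4 NF-kB members were higher and 1 lower and 1 hillock member was higher. In cKO replicate 2, cluster 11 held 81.5% of these cells, while cluster 10, led by Ces1f, held 79.7%, 52.0% and 61.6% in the other 3 libraries.

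The difference between the effect of genotype in secretory-like and in basal-like traced cells was tested itself, and 4 of 13605 genes passed in edgeR (6 in DESeq2). For Fabp5 (ENSMUSG00000027533, chromosome 3, 10012548 to 10016607) the effect was larger in secretory-like cells by log2 2.83 (SE 0.16, adjusted p = 3.21e-05). It ended with cluster 25 and the proliferating basal-like cluster left out together (log2 1.26, adjusted p = 0.904), and neither was left out alone in this test. Only cluster 25 is secretory-like. Fabp5 is among its leading genes, and it held 7 and 3 traced cells in cKO replicates 1 and 2 and 0 in the controls. For the carboxylesterase gene Ces1f (chromosome 8, 93256236 to 93279747) the difference was -1.62 (SE 0.17, adjusted p = 0.00651), with 287, 108, 156 and 42.0 CPM in secretory-like cells. The gastric lipase Lipf (adjusted p = 6.75e-08) and Sbpl (adjusted p = 0.000203) also passed. Lipf came almost wholly from 9 traced basal-like cells of control replicate 1 and 23 traced secretory-like cells of cKO replicate 2, so no fold is given. Sbpl came from 28 and 31 cells of the same kind in the same libraries. With the barcodes of several cell types kept, which then made up most traced secretory-like cells of control replicate 2, 0 genes passed. Among genes that did not pass, Mfge8 (log2 1.00), Ncf1, Jun (0.60), Ccl20 (3.80) and Kctd12 (0.71) were nearest on the higher side and Plaur (-1.42), Hist1h1b, Crip1 (-0.76), Pclaf and Lmna (-0.71) on the lower. Of 33 lists, 9 passed. The difference covered 13605 genes, against 11195 tested in traced secretory-like cells alone. Members with few counts there could thus enter, and their difference then largely restates the basal-like effect. S phase (1 of 39 above 0, median -0.64, adjusted p = 3.57e-14) and G2 and M phase genes (6 of 52, median -0.70, adjusted p = 5.33e-12) had lower effects in secretory-like than in basal-like cells, as did mitochondrially encoded genes (0 of 13, 7.47e-11), cholesterol synthesis (6 of 23, 1.88e-06) and oxidative phosphorylation (6 of 38, 0.0282). P53 targets (0.0212), immediate early genes and basal identity (0.0245 each) had higher effects. The goblet list passed as higher (2.59e-05) with a median of -0.02, a mean of 1.06 and 8 of 18 members above 0. The adjusted p = 0.709 with an estimated correlation for S phase, G2 and M phase, mitochondrial, cholesterol, goblet and immediate early genes, and 0.863 for the other 3.

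In untraced basal-like cells, which were not listed as tdTomato-positive, the make-up of the class differed between libraries. Cluster 7, of low depth, held 46.2% and 20.9% of them in the controls and 12.3% and 9.14% in the cKO mice, and cluster 4 held 56.5% in cKO replicate 2 and at most 5.83% in the other 3 libraries. Whether this accounts for the lists below was not tested. Cyp51 stood at 19.8 ± 3.47 and 35.7 ± 0.079 CPM (log2 0.84), and Msmo1 and Sqle had log2 fold changes of 1.12 and 1.02. The cholesterol list rose (21 of 23 above 0, median 0.44, camera adjusted p = 1.41e-09; adjusted p = 0.581 with an estimated correlation), with 0 members passing adjusted over the list alone. The hillock and squamous list rose (14 of 15, median 0.48, adjusted p = 3.16e-07; adjusted p = 0.581 with an estimated correlation), with Krt4 at 93.5 ± 16.7 and 180.2 ± 3.43 CPM. Tight junction and adhesion genes rose (20 of 24, median 0.29, adjusted p = 3.41e-05; adjusted p = 0.581 with an estimated correlation), with the desmosomal cadherin Dsg3 at log2 1.46, and lost the call without cKO replicate 1 (0.0519). Keratins rose (12 of 13, median 0.40, adjusted p = 7.62e-05; adjusted p = 0.799 with an estimated correlation) and lost the call without control replicate 2 (0.0973). The MHC class II list rose (12 of 12, median 1.00, adjusted p = 3.41e-05, or 0.819 with an estimated correlation) and fell without cKO replicate 2. S phase (33 of 38, median 0.47, 7.40e-05) and G2 and M phase genes (34 of 43, median 0.26, 0.0406) rose (adjusted p = 0.927 with an estimated correlation for each). Both lay lower without control replicate 1 (0.212 and 0.00707) and without cKO replicate 2 (0.193 and 2.28e-08). S phase lost the call under the other naming (0.126, median 0.14), and G2 and M phase without the proliferating cluster (0.896, median 0.10). The ciliated list rose (11 of 13, 0.0398; adjusted p = 0.799 with an estimated correlation) and lost the call without control replicate 1 (0.261), without cKO replicate 2 (0.131) and under the other naming (0.375, median 0.19). Immediate early genes rose (20 of 27, 0.0488; adjusted p = 0.927 with an estimated correlation) and lay lower without control replicate 1 (0.462) and without cKO replicate 1 (0.0707), and lost the call without the proliferating cluster (0.0570, median 0.20) and under the other naming (0.602, median 0.12). The other 22 of 31 lists had adjusted p from 0.0599 to 0.895. Some of them passed under an alternative, since 10 lists passed under the other naming (7 higher and 3 lower) and 12 with sex as a term. EdgeR called 0 of 11001 genes, against 235 higher and 224 lower at an unadjusted p under 0.05, and DESeq2 called 2. With sex as a term edgeR called 75, without control replicate 1 it called 1, without cKO replicate 1 34, and without cKO replicate 2 85. The smallest p belonged to Cryab, a small heat shock protein (log2 1.97), Tpm2, a tropomyosin (1.55), S100g (1.73), Ahnak2 (1.34) and Tmem267 (2.08), and to Lyz2, a lysozyme (-1.51), Arhgap24 (-1.31), the transcription factor Sox9 (-1.29), Tll1 (-3.62) and Tsc22d3 (-0.97), each at an adjusted p of 0.981.

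The effect of genotype did not pass as different between traced and untraced basal-like cells for any of 13627 genes in edgeR, against 234 higher and 318 lower at an unadjusted p under 0.05 and 1 gene in DESeq2. Tg, thyroglobulin, came nearest (adjusted p = 0.0954) and was measured almost wholly in untraced cells of control replicate 2. It was followed by Nupr1 (log2 1.26, adjusted p = 0.169), Edn2 (1.5), Sox9 (1.47) and Igkc (1.17), and on the lower side by Lipf, Bpifa1 (-1.15), Wfdc18, Ahnak2 (-0.87) and Slc23a2 (-0.80), at adjusted p from 0.387 to 0.813. Of the lists, 9 passed. G2 and M phase genes had a larger effect in traced cells (46 of 52, median 0.63, camera adjusted p = 0.000143, or 0.787 with an estimated correlation), while S phase did not pass (0.0536). Not all 52 were measured in untraced cells alone. Mitochondrially encoded genes (13 of 13, 3.56e-06), the MHC class II list (10 of 13, 1.44e-05), NF-kB (20 of 26, 0.00101) and interferon genes (26 of 37, 0.0254) also had larger effects in traced cells. Immediate early genes (2 of 27, median -0.24, 1.76e-10), goblet (5 of 15, 0.000720), tight junction (6 of 25, 0.00318) and heat shock genes (2 of 15, 0.0458) had smaller ones. The cholesterol, keratin, and hillock and squamous lists were not among the 9. They rose in traced and in untraced cells, so their rise was not confined to traced cells. Untraced cells can include cells with little tdTomato. The smallest adjusted p of any list = 0.757 with an estimated correlation.

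Within the controls, traced and untraced basal-like cells differed in 95 genes (60 higher and 35 lower in traced cells, of 13627). The numbers were 142 and 166 without the proliferating cluster, 79 and 93 under the other naming, and 30 and 21 with doublets kept. The cells compared lay in different clusters. Cluster 6, which Calml3 and Krt7 lead, held 17.7% and 6.48% of traced and 0.73% and 0.49% of untraced control basal-like cells, and cluster 7, of low depth and led by Lars2 among others, 9.57% and 0.94% against 46.2% and 20.9%. Squamous genes were higher in traced cells. Lgals7, a galectin of stratified epithelium (chromosome 7, 28863853 to 28866284), had a log2 fold change of 2.43 (SE 0.20, edgeR adjusted p = 0.000963), the calmodulin-like Calml3 of 2.22 (SE 0.22, 0.00252), Krt4 of 1.29 (SE 0.13, 0.00252) and Krt13 of 2.00 (SE 0.21, 0.00319). The Lgals7 call ended with the stricter filter on cells (log2 1.17, SE 0.49, 0.505), at the raised resolution (1.07, SE 0.32, 0.190) and without the proliferating cluster (0.99, SE 0.36, 0.176). Those of Calml3 (0.74, SE 0.25, 0.341) and Krt13 (0.46, SE 0.19, 0.417) ended with doublets kept. Lipf passed (0.00252) from 1 library, at 355 CPM in traced cells of control replicate 1 against 0.513 CPM in those of control replicate 2 and 1.06 and 0.497 CPM in untraced cells. Lower in traced cells were surfactant protein Sftpa1 (chromosome 14, 41131782 to 41136452; log2 -1.55, SE 0.11, 0.000633), transferrin Trf (-0.97, SE 0.09, 0.00252), Apoe (-0.77, SE 0.08, 0.00410), Lars2 (-1.61, SE 0.18, 0.00473) and the immunoglobulin gene Igkc (-1.41, SE 0.16, 0.00515). Sftpa1 leads a secretory-like cluster and Igkc an immune-like one, and untraced cells had less depth, so RNA from other cells was not excluded as the source of these differences. The hillock and squamous list rose (17 of 18, median 0.96, camera adjusted p = 2.21e-27), as did keratins (13 of 15, 4.25e-18), tight junctions (23 of 25, 7.26e-09), G2 and M phase (48 of 52, 3.24e-06), S phase (32 of 39, 0.000123), goblet (0.00133), oxidative phosphorylation (0.0180), basal identity (15 of 24, 0.0200), heat shock and NRF2 genes (0.0498 each). Mitochondrially encoded genes fell (0 of 13, median -0.42, 8.07e-18), as did NF-kB genes (6 of 26, 1.04e-06) and the tuft, interferon and MHC class II lists (0.00477 each). The smallest adjusted p of any list = 0.35 with an estimated correlation. The cells compared differed in depth, with a median of 20495 UMIs in traced and 6318 in untraced basal-like cells of control replicate 1, and 17631 and 7323 in control replicate 2.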

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

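Of the tests of explanations below, all but that of marked doublets were chosen only after the result was seen. The genes Lipf (adjusted p = 6.75057e-08), Fabp5 (adjusted p = 3.21172e-05), Sbpl (adjusted p = 0.000202681) and Ces1f (adjusted p = 0.0065078) are listed because the effect of genotype differed between traced basal-like and traced secretory-like cells by edgeR's test of the difference itself. Lipf had 7602 UMIs in 9 traced basal-like cells of control replicate 1 and 20469 UMIs in 23 traced secretory-like cells of cKO replicate 2. DESeq2 did not call it, and with doublets kept its adjusted p was 0.876. Sbpl, with 14519 UMIs in 28 cells and 30875 UMIs in 31 cells, came from the same libraries and classes, was not called by DESeq2, and had 0.915 with doublets kept. Fabp5 stood at 19.0, 38.4, 315 and 317 CPM before TMM scaling in traced secretory-like cells and at 10.5, 16.1, 21.1 and 19.96 CPM in basal-like cells. Its call ended with cluster 25 and the proliferating basal-like cluster left out together (adjusted p = 0.904), under the other naming (1.00) and with mixed profiles kept (0.562). Ces1f leads cluster 10, which held 11.1% of traced secretory-like cells in cKO replicate 2 and 79.7%, 52.0% and 61.6% in control replicate 1, control replicate 2 and cKO replicate 1. Its call ended under the other naming (0.500) and with mixed profiles kept (0.702). In that last setting most traced secretory-like cells of control replicate 2 were mixed profiles.

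Cell cycle genes were higher in traced basal-like cKO cells. A larger share of cells in the proliferating cluster as the whole cause is argued against for S phase genes, whose median log2 fold change kept 0.85 of its size without that cluster (0.79 to 0.67). Cycling cells outside that cluster are not covered by this test. For G2 and M phase genes a larger share of the cluster stays open, since 0.39 of the median was left (0.99 over 52 members to 0.39 over the 40 still measured), or 0.44 over the same 40 members. Under the other naming, 0.23 of the G2 and M phase median was left over the same 37 members, and 0.55 of the S phase median over the same 38. Spread between animals stays open too: with the correlation between members estimated at 0.283, the G2 and M phase list had an unadjusted p of 0.0337 and an adjusted p of 0.597. A candidate explanation in the genotype, more cycling basal-like cells after loss of Mettl3, therefore cannot be told apart from differences between 4 animals.

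MHC class II genes were high in cKO replicate 2, the animal with the most immune-like cells. RNA or doublets from the immune-like cells as a pool are argued against as the source. In traced basal-like cells 7 class II genes stood at a median of 7.69% of their level in immune-like cells. That was 23.6 times the 0.326% of 14 immune cell markers. The pool mixes several immune types, and RNA of those rich in class II genes alone was not tested. The genotype as the whole cause stays open. Of the MHC class II list, which also holds class I genes, 0 of 13 members lay above both controls in cKO replicate 1, against 13 of 13 in cKO replicate 2. However, that test sets a male against a female control, and 10 of 13 lay above the male control. An infection or inflammation of that animal may account for the pattern, as may its sex together with the genotype, and neither was tested.

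Barcodes with RNA of several cell types made up 1239 barcodes in control replicate 2, 39.3% of those left after the doublet step. Droplets with 2 cells are argued against. Counts varied between 1224 of these barcodes, all of the same cluster, with a variance over mean of 1.10 at the median gene. Random pairs of cells had 12.1, a bound chosen after the result. The pairs were drawn over all clusters, so part of that gap is built in. Within the largest kept cluster of that library the value was 3.44. The prediction written earlier, under 20% of marked doublets of the other 3 libraries with such markers, gave 17.2% (15 of 87) with an interval of 10.0 to 26.8 that spans the bound, and 41.4% in cKO replicate 2. A shared pool of free RNA would give such a low value, since every droplet then holds a like profile. Free RNA spread evenly over the suspension would also enter the other droplets of that library. The 365 cells of cluster 5, 190 of them from control replicate 2, had a median of 0.108 of their library's median UMIs. Of these cells, 0.3% held the markers of several types together, but so few UMIs lower that share by themselves, so it decides nothing. The depth argues against an evenly spread pool of that amount. Droplets of such depth hold fewer UMIs in all than the median of 13364 in the barcodes of several cell types. No biological explanation was tested, and the barcodes of several cell types had a median of 13364 UMIs against 16717 in the analysed cells of that library.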

How the results depend on the processing

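Of the results below, those with mixed profiles kept, the other naming, the common tdTomato floor or clusters left out, all of ciliated-like cells, and lists in untraced cells or in differences were chosen only after the data were seen. Over all alternatives, 109 counts and levels stayed on the same side, 31 went past the threshold, 14 moved by over 1.5 times and 12 lost it. For single lists the numbers were 1186 the same, 87 now past it, 156 no longer past it, 142 not past it on either side with another sign and 31 reversed, and for named genes 740, 178, 18, 3 and 1. Some results could not move. Mixed profiles kept left basal-like and ciliated-like cells as they were, and the other naming left ciliated-like cells as they were. The Mettl3 level was counted as the same throughout, without a comparison. Where a cause is not named below, the cause was not tested.

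Without the filter on low counts, called genes numbered 488 in traced basal-like (0 with it), 264 in traced secretory-like (0), 105 in untraced basal-like (0) and 108 in ciliated-like cells (0), 51 for the difference by tracing (0), 560 for tracing in controls (95) and 135 for the difference by class (4). DESeq2 gave 135, 17, 2 and 2 in the 4 genotype tests and 1 for the difference by tracing. Leaving out a library gave 0 to 158 genes in traced basal-like, 0 to 264 in traced secretory-like, 0 to 85 in untraced basal-like and 0 to 99 in ciliated-like cells, and 0 to 1 untraced class shares; the lone animal left in a group is then assumed to vary like the other group. Traced secretory-like cells had 2 genes with the common floor and 4 when thinned. The other naming gave 1 gene in untraced basal-like cells, 17 for the difference by tracing, 172 for tracing in controls and 2 for the difference by class. Left-out clusters gave 7 and 308 for the tests by tracing, mixed profiles kept gave 0 for the difference by class (and left basal-like cells as they were, since those clusters took other names), a raised resolution gave 1 for the difference by tracing, and doublets kept gave 51 for tracing in controls.

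With the replicate number as a block, calls numbered 141, 70, 75 and 17 in traced basal-like, traced secretory-like, untraced basal-like and ciliated-like cells. Labels do not say that the numbers pair the animals, and the correlations of same-numbered deviations were 0.140, 0.205, 0.334 and 0.127. The numbers coincide with sex. With the block 11, 7, 12 and 15 lists passed in the same order, where 10, 5, 9 and 14 did.

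With an estimated correlation 0 lists passed in each of the 7 list tests, where 10, 5, 9, 14, 9, 15 and 9 did, and fry called 0 in the 4 of genotype. In traced secretory-like cells 8 lists passed with traced and untraced cells together and 8 with mixed profiles kept, where 5 did. With the other naming 3 passed, and with clusters left out the same 3. These alternatives hold the same cells in that class, so they are the same check there. Leaving out a library gave 5 to 14 lists there and 8 to 18 in ciliated-like cells.

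Some lists changed direction when a library was left out, given here with the range of adjusted p over the 4 libraries left out. In traced basal-like cells, interferon (4.47e-22 to 0.776) and MHC class II (1.46e-41 to 0.255) lay lower without cKO replicate 2. In traced secretory-like cells, interferon (3.76e-26 to 0.174) and MHC class II (8.30e-37 to 0.149) did so too, S phase (0.00612 to 0.337) and G2 and M phase (0.000597 to 0.912) passed as lower without control replicate 1, immediate early genes (0.0112 to 0.132) without cKO replicate 1, and oxidative phosphorylation (0.00146 to 0.813) without control replicate 2. With mixed profiles kept, basal identity (0.261), ciliated (1.44e-07), oxidative phosphorylation (4.48e-07) and ribosomal genes (1.25e-10) lay lower there. Most such cells of control replicate 2 were then mixed profiles.

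In untraced basal-like cells, S phase (2.49e-19 to 0.212) and G2 and M phase (7.86e-21 to 0.00707) lay lower without control replicate 1 and without cKO replicate 2, and MHC class II (9.84e-35 to 0.0494) without cKO replicate 2. Immediate early genes (5.96e-15 to 0.462) lay lower without control replicate 1 and without cKO replicate 1, and extracellular matrix genes (0.0365 to 0.695) without control replicate 1. Interferon (0.00190 to 0.0836) and NF-kB (7.60e-05 to 0.144) passed as higher without cKO replicate 1. Under the other naming, G2 and M phase (0.310) and extracellular matrix genes (0.0361) lay lower.

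In ciliated-like cells, MHC class II (3.01e-65 to 0.918) and G2 and M phase (1.10e-06 to 0.203) lay lower without cKO replicate 2, and interferon (5.98e-17 to 0.326) without it and without control replicate 1. Higher were immediate early genes (1.48e-14 to 0.253) without cKO replicate 2, NF-kB (2.60e-08 to 0.328) without cKO replicate 1, and oxidative phosphorylation (1.58e-07 to 0.707) without control replicate 1. For tracing in controls, Lipf had log2 -0.75 at the raised resolution. An alternative with traced cells of at least 2 tdTomato UMIs was not run, because the listed floors lie above it.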

Other observations

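The tests of ciliated-like cells, and all list tests on them, were chosen only after the data were seen, because traced ciliated-like cells were too few in some libraries. With traced and untraced cells together there were 28, 139, 181 and 108 ciliated-like cells, of which 13, 37, 16 and 32 were traced and 16, 55, 69 and 14 lay in cluster 14, of low depth. This make-up differs between libraries, and its part in the changes below was not tested. Every list here and in the next paragraph had an adjusted p of at least 0.556 with an estimated correlation. Ribosomal protein genes fell in cKO mice (0 of 40 above 0, median log2 -0.60, camera adjusted p = 6.68e-16), with Rps28 at 574 ± 340 and 284 ± 31.8 CPM. Without control replicate 1, the library with the fewest such cells, the call ended (adjusted p = 0.123). Mitochondrially encoded genes rose (13 of 13, median 0.47, 4.03e-06) and lost the call without the same library (0.173). Growth factor response genes fell (EGFR list, 4 of 15, median -0.33, 0.000266), with the ligand Areg at 61.2 and 18.6 CPM and Phlda1 at 371 and 122 CPM, and without cKO replicate 2 had 0.0558. The BMP and TGF-beta list fell (3 of 14, 0.0123), with Id1 at 217 and 98.2 CPM and Id3 at 64.5 and 36.3 CPM, and lost the call without control replicate 2 (0.0973) and without cKO replicate 2 (0.709).

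Other lists passed too. Keratins (2 of 12, 2.10e-06) and basal identity (4 of 21, 4.19e-05) fell and lost the call without control replicate 1 (0.325 each) and without cKO replicate 2 (0.449 and 0.354), and Krt15 stood at 1238, 488, 420 and 244 CPM. Club genes fell (6 of 25, 0.000296) and had 0.851 without cKO replicate 2. Extracellular matrix genes (0.00169) fell and had 0.0558 without cKO replicate 2, and stress response genes (0.00321) fell and had 0.0850 without cKO replicate 1. Wnt genes (0.0194) fell and lost the call without control replicate 1 (0.247) and without cKO replicate 2 (0.231). Immediate early genes (0.0399) fell, had 0.253 without control replicate 2, and rose without cKO replicate 2 (0.0132). The MHC class II list (12 of 12, 1.83e-06) and interferon genes (0.0154) rose and lay lower without cKO replicate 2, interferon genes also without control replicate 1. Immune cell markers rose (3 of 5, 0.000752) and had 0.247 without control replicate 1. EdgeR called 0 of 11820 genes, against 102 higher and 144 lower at an unadjusted p under 0.05, and DESeq2 called 2. With sex as a term it called 17, without cKO replicate 1 99 and without cKO replicate 2 63. Nearest on the higher side were Tmem267 (log2 2.25), Wdfy1 (1.62), Tenm4 (2.84), Gm7467 (2.28) and Rep15 (2.13), and on the lower side the hyaluronan receptor Cd44 (-1.53), 5330417C22Rik (-1.43), Ifi27l2a (-2.15), the prostaglandin synthase Ptgs2 (-2.0) and Sftpb (-4.86), each at an adjusted p of 1.00.

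A small secretory-like cluster was led by Ccl20, Spib, Ccl9, Ubd and Fabp5, of which Spib, Ccl20 and Ccl9 are known from the epithelium over lymphoid follicles. It held 0 and 1 cells in the controls and 23 and 12 in the cKO mice. Tuft-like cells numbered 70 of the 480 untraced cells of control replicate 1, and 4, 2 and 2 in the other 3 libraries. Neuroendocrine-like cells numbered 2, 4, 8 and 6, traced and untraced together.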
